A study of Oryza sativa with 6 samples.

How the data were processed

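Expression was measured on the Affymetrix Rice Genome Array in embryonic axes of mature rice seeds (Oryza sativa cultivar Nipponbare) after controlled deterioration, a treatment that ages seeds in warm and humid air. Per the labels' protocols, seeds spent 3 days at 25 °C and 85% relative humidity, then 14 days at 40 or 45 °C and 85% relative humidity, and lastly 3 days at 25 °C and 32% relative humidity. Another label field gives 15 days for the warm step, and which is right was not settled. Total RNA (50 ng) was amplified and labelled with biotin, per the labels' protocols. There were 3 arrays per temperature. A control at 25 °C, named in the labels, was not analysed here.

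The deposited values are log2 expression values, 1 per probe set and array, which the authors made with GCRMA, per the submitters' processing notes. As a method, GCRMA corrects background, applies quantile normalization between arrays and summarises the probes of a probe set. Its version is not given in the sources used here. That the scale is log2 was checked on the values, which have a lowest value of 0.563 and a highest of 14.6 over the arrays. All value columns of the table belonged to the 6 samples. No detection calls were used, so probe sets near the floor could be set aside only by their level, and the number of arrays limits the precision.

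The table holds 57381 probe sets, of which 123 are controls. Of the 57258 others, 22436 had 1 gene in the platform annotation, 95 had several and 34727 had none listed. All 17905 genes were found in the gene name table of assembly ASM3414082v1, which was used for names alone, and 2450 had a name other than a locus number. No coordinates are given, because the build behind the array design is not given in the sources used here. Names are those of the annotation and its synonyms.

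Probe sets with a mean log2 value of at least 4 over the 6 arrays were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), 45 °C against 40 °C, two-sided, with Benjamini-Hochberg adjustment at 0.05. Temperature was the only term in the model. No label says that the 3 samples of a group came from separate seed lots, so p-values measure the spread between these samples, which may be technical. The step was tested on simulated data: in 10 simulated tables of 22214 probe sets with 200 changed, 14.4% of log2 changes of 1 and 82.3% of log2 changes of 2 were recovered, with 5.30 false calls per table. A simulated list of 40 genes shifted by -0.3 was called in 10 of 10 tables, and 0 of 100 unshifted lists were called. In these tables probe sets varied independently of each other, with no common shift and no outlying array. They do not test list calls where genes vary together, as in the endosperm list (estimated correlation 0.651). The recovered shares likewise hold for such tables alone.

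Gene lists were tested with camera at a preset inter-gene correlation of 0.01, on the probe set of highest mean for each of 11639 genes, with Benjamini-Hochberg adjustment over the lists. The test with an estimated correlation and fry were run beside it. Members were also adjusted over their list alone, without correction over the lists. A given p passes more easily in a short list, so such passes are not comparable between lists. Before the data were examined, 18 lists were fixed by patterns on gene descriptions and symbols. The name table holds symbols without descriptions, so only the symbol patterns applied; 4 of the 18 lists (cytosolic ribosome, histones, oil bodies and respiration) had fewer than 3 tested genes and were not tested. A further 19 lists were made from the symbols after the name table was seen and before any test. The patterns of 2 of these (endoplasmic reticulum folding, thioredoxins and glutaredoxins) were narrowed after first values had been seen, because they had caught genes of other families with similar names.

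Named genes followed a rule fixed before the data were examined. Among probe sets with 1 gene, past the adjusted threshold and with the groups not overlapping, the 10 of largest change in each direction were to be named, together with up to 2 members per list and direction. Where fewer than 10 passed, those of smallest p filled the places and are described by value only; where no member of a list passed, the member of smallest p is given. The same rule was applied a second time to genes with a name, a choice made before any test.

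RNA quality was read from the rice control transcripts, as the log2 difference between 3-prime and 5-prime probe sets of the same transcript, in the 5 transcript sets with a mean of at least 4 in every part; 2 sets were left out as too dim. Extracted RNA mass came from the labels. Both were compared with exact two-sided permutation tests, for which 3 against 3 cannot go below p = 0.1. Arrays were compared by Pearson correlation and principal components over the tested probe sets, and no pair of arrays held more than 0.870% identical values.

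Alternatives fixed in advance were no filter, a filter at 6, centring each array on its median, a further quantile normalization, no intensity trend, array quality weights, the replicate number as a block, leaving out each array in turn, a minimum log2 change of 1, a threshold of 0.01, and leaving out probe sets with shared targets. For lists they were the estimated correlation, fry, ranks and the mean of all probe sets of a gene. Cyclic loess normalization, the mean 3-prime to 5-prime difference as a covariate, and the place of a list's median among 10000 random lists matched on mean expression were added after seeing the data.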

Results

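Transcript levels were compared between embryonic axes of rice seeds aged for 14 days at 40 °C (3 arrays) and at 45 °C (3 arrays), both at 85% relative humidity. The comparison asks which transcripts differ between seeds aged under the milder and the harsher temperature. Of the non-control probe sets, 22214 reached the expression minimum and were tested.

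The arrays of the 2 groups differed in the level of the tested probe sets, but not in the same direction over all probe sets. Over all non-control probe sets, array medians were 3.08 to 3.13 at 40 °C and 3.20 to 3.21 at 45 °C. Over the tested probe sets, array medians lay between 6.45 and 6.55 at 40 °C and between 6.23 and 6.25 at 45 °C. The median log2 change of tested probe sets was -0.17 (0.08 over all non-control probe sets, without the expression minimum) and that of the 11639 genes was -0.26, with 78.7% of genes lower at 45 °C. The gene median was -0.01 after centring each array on its median, -0.07 after a further quantile normalization and -0.10 after cyclic loess. List medians are therefore also given as differences to the median of all genes. This reference takes no account of expression level, on which the change depended, so such differences are not comparable between lists of unlike level. Probe sets with a mean between 6 and 7 had a median change of -0.26, those between 10 and 12 of -0.16, and those between 4 and 5 of 0.09.

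**Figure D1:**
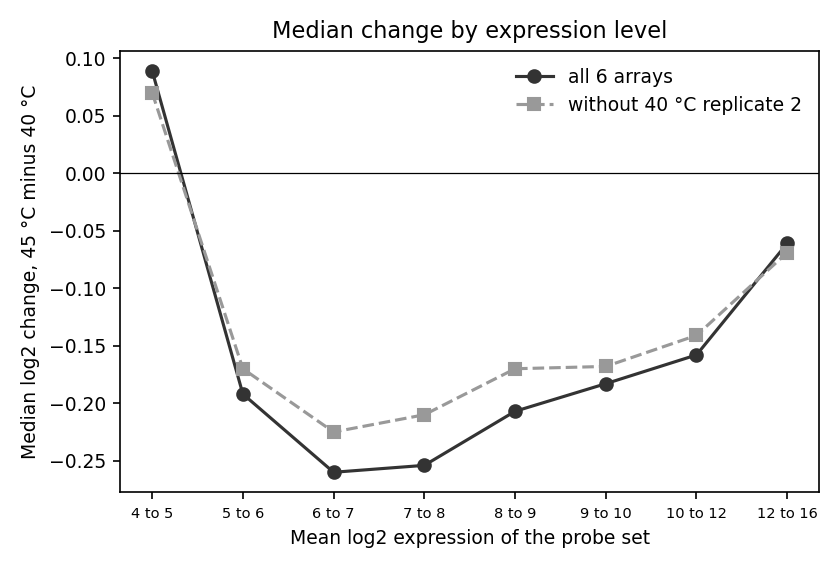
Median log2 change (45 °C minus 40 °C, vertical axis) of tested probe sets in classes of mean log2 expression (horizontal axis), for all 6 arrays and without replicate 2 at 40 °C. The median is 0.09 in the dimmest class and -0.26 between 6 and 7.

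Replicate 2 at 40 °C stood apart from the other arrays. Its correlation with the other 40 °C arrays was 0.927 at the lowest, whereas replicates 1 and 3 correlated at 0.982. Correlations were 0.939 to 0.946 within the 45 °C group and 0.895 to 0.948 between groups. The control transcripts differed most in this array: the mean 3-prime minus 5-prime difference was 2.99 log2 units, against 1.74 and 1.92 in the other 40 °C arrays and 1.66 to 2.03 at 45 °C. Between groups this difference was 2.21 ± 0.68 (SD, n = 3) at 40 °C and 1.78 ± 0.22 (SD, n = 3) at 45 °C, with an exact permutation p of 0.5. The mean 3-prime minus middle difference was 1.65 ± 0.78 (SD, n = 3) at 40 °C and 1.58 ± 0.35 (SD, n = 3) at 45 °C, with an exact permutation p of 1, but it was higher on all 3 arrays at 45 °C than on the 2 other arrays at 40 °C, by a mean of 0.37. In 1 of the 5 transcript sets, ubiquitin, the 3-prime minus 5-prime difference was lower on all arrays at 45 °C (mean -1.43) than on all arrays at 40 °C (mean -0.64). Extracted RNA was 58.7 ± 8.14 µg (SD, n = 3) at 40 °C and 48.7 ± 7.02 µg (SD, n = 3) at 45 °C, with an exact permutation p of 0.3; none of these tests can go below 0.1.

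**Figure D2:**
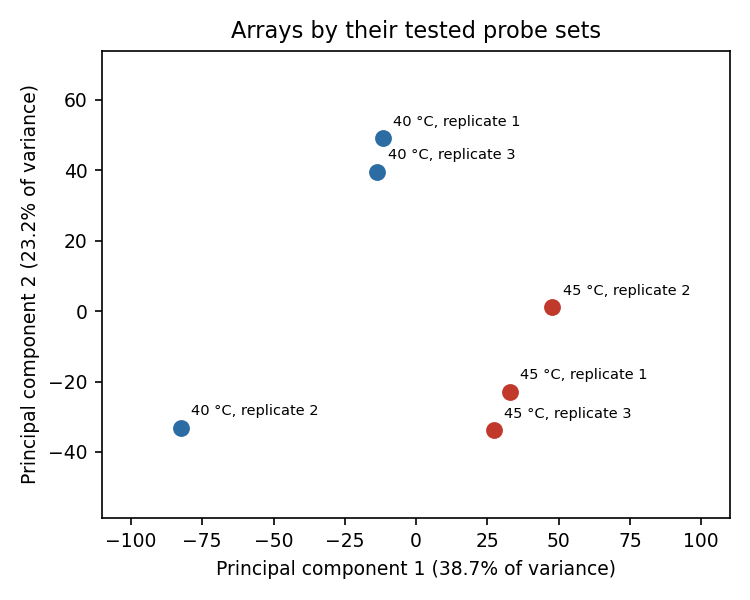
Principal components 1 and 2 of the 6 arrays over the tested probe sets, coloured by temperature (blue 40 °C, red 45 °C). Component 1 holds 38.7% of the variance, and replicate 2 at 40 °C lies at -82.5 on it while the other arrays lie between -13.7 and 47.8.

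The largest differences with small p among genes with a name were mostly toward lower levels at 45 °C. The transcript of ML, also named salT, a mannose-binding lectin known from salt stress, had a mean log2 value of 7.63 ± 0.27 (SD, n = 3) at 40 °C and 5.18 ± 0.41 (SD, n = 3) at 45 °C, a log2 change of -2.46 ± 0.30 (SE), or 5.49-fold higher at 40 °C. The zinc finger gene OsC3H16 had a change of -1.88, CHLG, which encodes chlorophyll synthase, of -1.61, the oxophytodienoate reductase gene OPR4 of -1.57, and the calcium-dependent kinase gene CPK24 of -1.52. OSPIN10a, an auxin efflux carrier also named OsPIN3a, was the clearest in the other direction, with 7.71 ± 0.42 (SD, n = 3) at 40 °C and 9.47 ± 0.26 (SD, n = 3) at 45 °C. Its log2 change was 1.76 ± 0.25 (SE), or 3.38-fold higher at 45 °C.

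No probe set passed the limma test at a Benjamini-Hochberg adjusted p of 0.05. The smallest adjusted p was 0.108, and the adjusted p of ML was 0.124 and that of OSPIN10a 0.13. At an unadjusted p under 0.05 there were 4256 probe sets, where chance alone gives about 1111; 1194 were higher and 3062 lower at 45 °C, so that 71.9% were lower. That share depended on the expression minimum and on scaling. Without a minimum 41.6% were lower (5813 higher, 4137 lower), and with a minimum of 6 the share was 88% (266 higher, 1948 lower). At the minimum used it was 24.7% after median centring, 42% after quantile normalization and 56% after cyclic loess. The groups did not overlap in 6370 probe sets, 28.7% of those tested, where chance gives 10% on average. That share was not computed after scaling, so it includes the common shift. The chance values of 1111 and 10% are averages that do not give the spread when probe sets vary together. Other splits of the arrays gave 451 to 1637 probe sets at an unadjusted limma p under 0.05. These splits place both temperatures in each group, so any temperature difference widens their within-group spread. Their counts therefore do not give the spread under chance either. With array quality weights, which gave replicate 2 at 40 °C a weight of 0.336, replicate 3 at 40 °C 3.74 and the others 0.771 to 1.32, 193 probe sets passed (15 higher, 178 lower), and without that array 69 passed (3 higher, 66 lower); 43 were called in both. With the 3-prime minus 5-prime difference of the control transcripts as a covariate 44 passed, all lower. Each of these settings reduces the influence of replicate 2 at 40 °C, which had the highest such difference (2.99, against 1.66 to 2.03). They are therefore not independent of each other, and their shared calls are not separate support. With array weights the 40 °C level rested mostly on replicate 3.

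Further named genes toward higher levels at 45 °C, none past the threshold, were the beta-tubulin gene RTUB-2 (1.15), the calmodulin-like gene CML17 (1.16), the homeodomain genes Hox11 (1.005) and Hox19 (0.79), OC-X (0.74), the actin-related gene ARP9 (0.70), OsCASPL2B1 (0.66), OsC3H18 (0.46) and the membrane protein gene OsPM19L1 (0.44), as log2 changes. Toward lower levels they were EX2 (-1.25), HMG3, a hydroxymethylglutaryl-CoA reductase (-0.74), HSP18.6 (-0.67, and -0.17 in its other probe set), pinA (-0.50) and HSP18.0 (-0.46). For RTUB-2 and OsC3H18, 2 of 2 other tested probe sets had the opposite sign, as did 1 of 1 for ARP9, OsPM19L1 and EX2. Among genes known here only by locus, LOC4346301 had a log2 change of -3.02, LOC4330904 of -2.73, LOC4341092 of -2.70 and LOC4324274 of 2.23. Each of these 4 loci had 1 group mean under the expression minimum of 4, so that the size of its change is uncertain: 3.08 at 40 °C for LOC4324274, and 3.51 for LOC4346301, 3.73 for LOC4330904 and 3.72 for LOC4341092 at 45 °C. The mean of Hox19 at 40 °C was 3.76, also under the minimum.

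**Figure D3:**
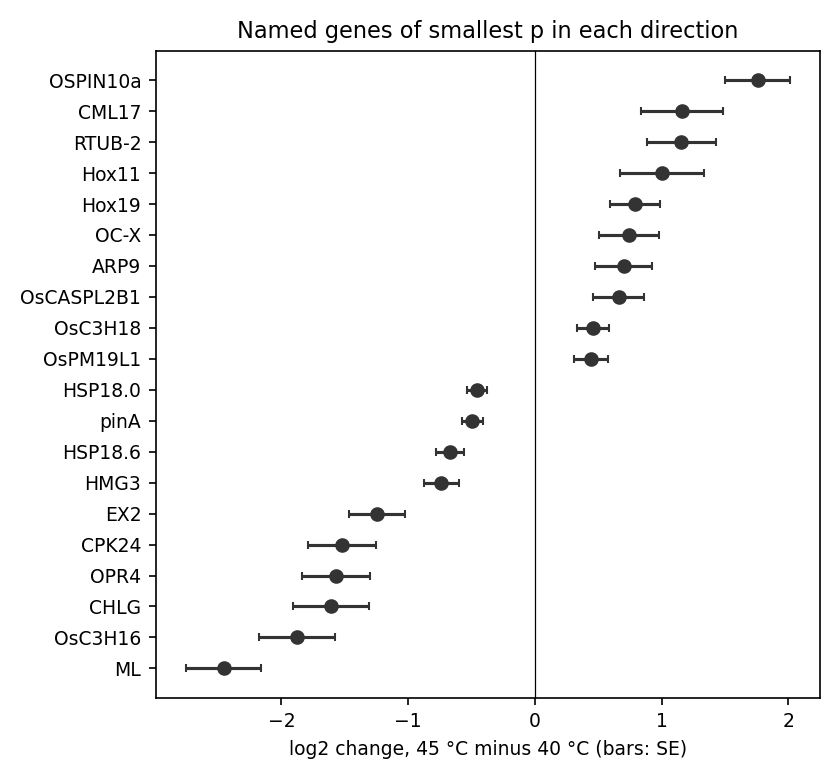
Log2 change (45 °C minus 40 °C, points) with its standard error (bars) for the 10 named genes of smallest p in each direction among those whose groups did not overlap. ML lies lowest at -2.46 and OSPIN10a highest at 1.76; no gene passed the adjusted threshold.

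Heat shock proteins and heat shock factors, the chaperones of protein folding and their regulators, made up the 1 list that camera called lower at 45 °C with the preset correlation (adjusted p = 0.0161). The call was lost with an estimated correlation (camera p = 0.018, adjusted p = 0.593), a setting in which no list passed. The correlation estimated for this list was -0.022, so the loss does not show that its members vary together. Of 39 measured members, 35 were lower and 4 higher. The median log2 change of the list was -0.32, against -0.18 for random lists matched on mean expression (central range -0.27 to -0.10). Its difference to the median of all genes was -0.06. This difference was -0.07 after quantile normalization and -0.02 after cyclic loess, and ranged from -0.11 to 0.05 when leaving out 1 array, above 0 without replicate 1 or 3 at 40 °C or replicate 3 at 45 °C. No member passed over all probe sets tested, while 9 passed adjusted over the list alone, all lower. Examples are HSP17.7 (-0.44 ± 0.10 SE), the disaggregase gene CLPB1 (-0.40 ± 0.09 SE) and the factor gene HSF1, also named HSFB2A (-1.01 ± 0.26 SE). Some members were listed through a synonym alone, such as ARD1 (-0.63) and HS1 (-0.84, also 1 of the 9). Whether these belong to the family was not checked. HSP18.0 had the smallest p of the list, but 2 of 2 other tested probe sets of this gene had the opposite sign. The list call was lost as well with the mean of all probe sets per gene (adjusted p = 0.101), after median centring (adjusted p = 0.881), after cyclic loess (adjusted p = 0.61) and without the intensity trend (adjusted p = 0.535). Without replicate 1 at 40 °C the adjusted p was 0.243, without replicate 1 at 45 °C 0.106, and without replicate 3 at 45 °C 0.14.

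Markers of endosperm, the starchy storage tissue beside the embryo, formed the 1 list that camera called higher at 45 °C with the preset correlation (adjusted p = 0.000391). With an estimated correlation the call was lost (adjusted p = 0.856). Of 8 measured members 7 were higher and 1 lower, with a median log2 change of 0.32, a difference of 0.58 to the median of all genes, and none passed over all probe sets or adjusted over the list alone. The seed allergen gene RA17 had a log2 change of 0.85 ± 0.44 (SE), and of 0.41 to 1.16 when leaving out 1 array. Replicate 2 at 40 °C held the lowest median of these markers, 8.46, against 9.995 and 10.09 in the other 40 °C arrays and 9.08 to 10.01 at 45 °C. Of the 9 marker genes on the array 8 reached the expression minimum, and RA14, the marker of highest signal, had mean log2 values of 11.23 at 40 °C and 11.22 at 45 °C. Without replicate 2 at 40 °C the median change of the list was -0.03 and the adjusted p 0.542, without replicate 3 at 45 °C the adjusted p was 0.0594, and with array weights it was 0.182.

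The other lists fixed in advance did not pass camera, with adjusted p from 0.305 to 0.986. With fry, which does not compare a list with other genes, translation factors (adjusted p = 0.00643), the proteasome list (adjusted p = 0.0118) and the abscisic acid list (adjusted p = 0.034) passed as lower. Late embryogenesis and dehydrin genes, which protect dry seeds, had a median change of -0.08, a difference of 0.18 to the median of all genes, with 6 of 7 lower; RAB16D (-0.52 ± 0.11 SE) was the 1 member that passed adjusted over the list alone. After median centring camera called this list higher (adjusted p = 0.00726). Before centring, its median lay at percentile 80.63 of random lists matched on mean expression, inside their central range of -0.324 to -0.006. The median of this list was 0.18 after median centring, 0.06 after cyclic loess and -0.14 to -0.05 when leaving out 1 array. In the abscisic acid list, 12 of 13 members were lower (median -0.37, -0.45 to -0.26 when leaving out 1 array, a difference of -0.10 to all genes), and the kinase genes OsSAPK1 (-0.45) and OsSAPK9 (-0.88) passed adjusted over the list alone. For the proteasome and ubiquitin list 9 of 11 were lower (median -0.30, a difference of -0.03 to all genes, but 0.03 after cyclic loess and -0.11 to 0.04 when leaving out 1 array), and OsRPT5a (-0.79 ± 0.15 SE) and OsRPN11 (-0.46) passed adjusted over the list alone. ADPRT-3, also named PARP3 (-0.35), was the 1 of 3 DNA repair genes to do so (median -0.16, but 0.10 after median centring, -0.42 without replicate 2 at 45 °C and 0.12 without replicate 3 at 45 °C). None passed in this way among 17 antioxidant genes (median -0.22, but 0.04 after median centring), where CAT-B, a catalase, had a change of -0.42 and 2 of 4 other probe sets of the opposite sign.

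No member passed adjusted over the list alone in the remaining fixed lists either. Medians were -0.29 for translation factors (6 genes, all lower; eIF-4A-1 at -0.36), -0.47 for lipid degradation (3 genes; PLD1 at -0.47), -0.09 for protein repair (6 genes; MSRB3 at -0.43), -0.03 for glutathione transferases (6 genes; GST-II at -0.13) and -0.02 for glycolysis and fermentation (4 genes; Adh2 at -1.70). The green tissue list of 4 photosynthesis genes had a median of -0.23, but 0.26 without replicate 1 at 45 °C and -0.50 without replicate 3 at 45 °C; its member of smallest p, AAP-S (-1.18), is listed through the synonym PSA alone. The aleurone list of 5 gibberellin and amylase genes had a median of -0.05, with AMY1.1 at -0.70. Leaving out 1 array gave medians of -0.29 to -0.20 for translation factors, -0.62 to -0.14 for lipid degradation, -0.20 to 0.01 for protein repair, -0.17 to -0.01 for glutathione transferases, -0.30 to 0.03 for glycolysis and -0.28 to 0.08 for the aleurone list. Log2 changes ranged from -0.62 to -0.31 for PLD1, from -1.10 to -0.15 for AMY1.1, from -0.44 to -0.20 for eIF-4A-1 and from -0.18 to -0.08 for GST-II, each range over the 6 arrays left out in turn. The mean of Adh2 at 45 °C was 3.68, under the expression minimum. Without a minimum the medians were -0.05 for lipid degradation, 0.08 for glycolysis and 0.13 for photosynthesis, and with a minimum of 6 that of photosynthesis was 0.245. These values include the common shift. The medians of protein repair, glutathione transferases, glycolysis and the aleurone list were above 0 after median centring, quantile normalization and cyclic loess, and that of photosynthesis after median centring. Camera, which compares a list with all other genes, placed these 5 lists higher, none past the threshold, although their medians were below 0. Of all 33 list medians tested, 18 changed sign under median centring, 15 under quantile normalization and 14 under cyclic loess.

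**Figure D4:**
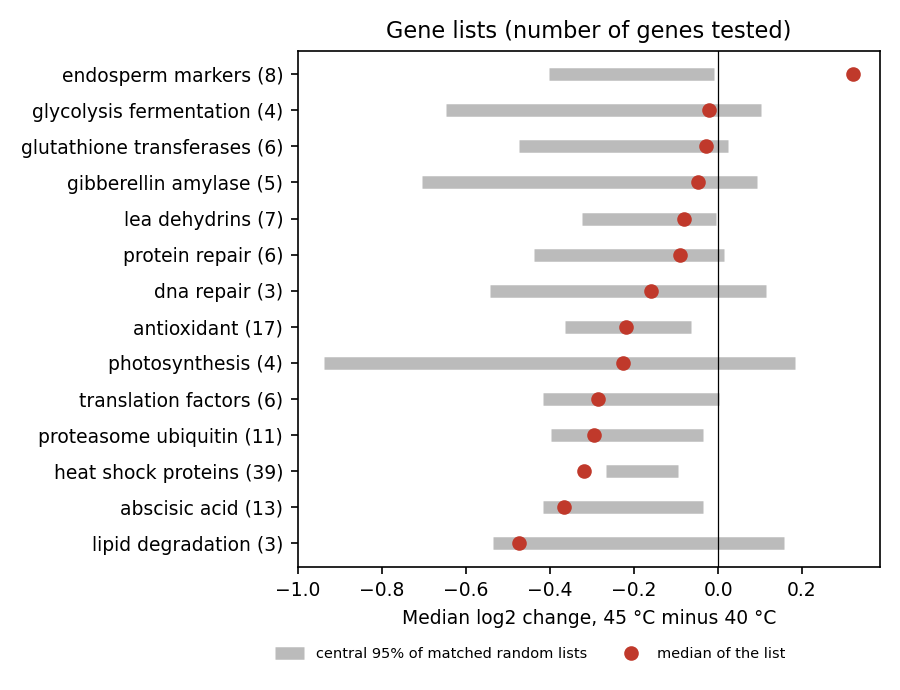
Median log2 change (45 °C minus 40 °C, red points) of the 14 tested lists fixed in advance, with the number of genes tested, over the central range of 10000 random lists matched on mean expression (grey bars). Heat shock proteins lie at -0.32, below their matched range of -0.27 to -0.10, and endosperm markers at 0.32, above theirs.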

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

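Cyclic loess, the covariate of the 3-prime minus 5-prime difference and the matched random lists were chosen after seeing the data; the cause of the changes given here was not tested, except where a filter changed the number of probe sets tested. The count of probe sets past the adjusted threshold was 0 without a filter, with a filter at 6, after median centring, quantile normalization or cyclic loess, without the intensity trend, with the replicate number as a block (smallest adjusted p 0.283), at a threshold of 0.01, with a log2 change of at least 1 and without probe sets of shared targets. It was 193 with array weights (15 higher, 178 lower), 44 with the covariate (44 lower), and 0 to 69 when leaving out 1 array in turn (0 to 3 higher, 0 to 66 lower); 69 was reached without replicate 2 at 40 °C. The count at an unadjusted p under 0.05 was 9950 without a filter (5813 higher, 4137 lower) and 2214 with the filter at 6 (266 higher, 1948 lower). The number of lists called higher was 3 without a filter, 4 after median centring, 3 after cyclic loess, and 0 with array weights, the covariate, the estimated correlation or fry; leaving out 1 array gave 0 to 1. The number called lower was 0 after median centring or cyclic loess, without the trend, with the estimated correlation and with the mean of all probe sets, and 9 with fry; leaving out 1 array gave 0 to 1. For the heat shock list the camera adjusted p was 0.881 after median centring, 0.535 without the trend and 0.61 after cyclic loess. It was 0.593 with the estimated correlation, 0.101 with the mean of all probe sets, and 0.00053 to 0.243 when leaving out 1 array. The call was kept without a filter (0.00476), with the filter at 6 (0.0109) and after quantile normalization (0.0381). The replicate block (0.00672), array weights (0.00953) and the covariate (0.00041) kept it too, and fry gave an adjusted p of 0.002. For the endosperm list it was 0.182 with array weights, 0.267 with the covariate, 0.856 with the estimated correlation, 0.564 with fry, and 1.72e-07 to 0.542 when leaving out 1 array. The direction was reversed, with a call, for late embryogenesis genes after median centring (camera adjusted p = 0.00726, higher). Type 2C phosphatases passed as lower with fry (adjusted p = 0.0272), while camera had placed them higher than other genes. Their median was -0.19 for both tests, so this is a difference in what is compared and not a reversal. For the other 31 lists, 512 of 620 values were the same, 14 gained a call and 92 moved. For 67 named gene results, 944 of 980 values were the same, 34 gained a call (24 with array weights, 7 without replicate 2 at 40 °C, 3 with the covariate), 2 moved and 0 reversed; the filter at 6 gives no value for dim genes. GST-II changed sign under median centring and cyclic loess. The group difference in the 3-prime minus 5-prime measure was -0.67 to -0.05 when leaving out 1 array, and that in extracted RNA -13.7 to -5.33 µg. For array similarity, the mean correlation within groups minus that between groups, the value was 0.0152, and 0.0069 without a filter. Without detection calls, signal over background limits what can be said of dim probe sets.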

Other observations

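The tests of matched random lists, of starting abundance, of the control transcripts, of array correlations, of endosperm markers in single arrays, of the hybridisation controls and of leaving out replicate 2 at 40 °C as an explanation were chosen after the result was seen. The counts over other splits of the arrays were planned.

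Among the 19 lists made from the gene symbols after the name table was seen, none passed camera, and adjusted p ranged from 0.263 to 0.986. Calcium-dependent and CBL-interacting protein kinases, which relay calcium signals, had 28 of 31 members lower at 45 °C, with a median log2 change of -0.41 (a difference of -0.15 to the median of all genes, but -0.01 without replicate 1 at 45 °C), and 5 members passed adjusted over the list alone: CPK24 (-1.52), CIPK12 (-1.55), CIPK14 (-1.44), CIPK21 (-1.37) and CPK13 (-1.05). In the list of protein folding in the endoplasmic reticulum, 11 of 11 members were lower (median -0.36, a difference of -0.10 to all genes, and -0.15 to -0.01 when leaving out 1 array), with OsPDIL1-4 at -0.72. With fry, which does not compare a list with other genes, both passed, as did stress transcription factors (adjusted p = 0.00643 for each), type 2C phosphatases (adjusted p = 0.0272) and kinesins (adjusted p = 0.034), beside 4 of the lists fixed in advance. Medians were -0.61 for kinesins (19 genes; -0.75 to -0.42 when leaving out 1 array), -0.47 for metallothioneins (4 genes; -0.59 to -0.38), -0.42 for stress transcription factors (9 genes; -0.48 to -0.21), -0.28 for autophagy (7 genes; -0.51 to -0.14) and -0.26 for auxin signalling (29 genes; -0.31 to -0.19). The medians of calcium kinases, endoplasmic reticulum folding, kinesins, metallothioneins and stress transcription factors lay below that of all genes under median centring, quantile normalization and cyclic loess, but 3 of the 5 depended on the expression minimum. Without a minimum the difference to all genes was 0.24 for stress transcription factors (median 0.08) and 0.10 for metallothioneins. With a minimum of 6 it was 0.001 for kinesins (median -0.24) and 0.07 for metallothioneins, and without replicate 1 at 45 °C it was 0.04 for stress transcription factors. Autophagy differed from all genes by -0.02 to 0.03 under these scalings and auxin signalling by 0.001 to 0.06. Among type 2C protein phosphatases 35 of 49 were lower (median -0.19, but 0.07 after median centring and -0.28 to -0.17 when leaving out 1 array), and OsPP2C39 (-1.63), OsPP2C54 (-1.24) and OsPP2C36 (-1.05) passed adjusted over the list alone; the means of OsPP2C39 (3.83) and OsPP2C54 (3.86) at 45 °C were under the expression minimum. So did ERR26, also named MT1A (-0.94), in metallothioneins, OsTIP2;2 (-0.51) in aquaporins and OPR4 (-1.57) in jasmonate genes.

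The other added lists had medians of -0.20 for jasmonate (17 genes), -0.20 for sucrose and trehalose metabolism (17 genes), -0.16 for cytochrome P450 enzymes (9 genes), -0.14 for ribosomal proteins (24 genes), -0.12 for thioredoxins and glutaredoxins (26 genes), -0.12 for mitochondrial membrane proteins (18 genes), -0.11 for DNA replication (15 genes), -0.11 for expansins (9 genes) and -0.08 for aquaporins (10 genes), each above 0 after median centring. Camera placed all of these except jasmonate higher than other genes, as it did type 2C phosphatases and auxin signalling, although their medians were below 0 and none passed. Ribosomal proteins passed as higher after median centring (adjusted p = 0.00726) and cyclic loess (adjusted p = 0.0165), and so did thioredoxins and glutaredoxins (adjusted p = 0.0405 and 0.038). Neither passed after quantile normalization. Before any scaling, the median of ribosomal proteins lay at percentile 70.37 of random lists matched on mean expression, and that of thioredoxins and glutaredoxins at 93.35. When leaving out 1 array the medians were -0.43 to -0.10 for jasmonate, -0.29 to -0.14 for sucrose and trehalose, -0.30 to -0.15 for cytochrome P450, -0.20 to -0.05 for ribosomal proteins, -0.17 to -0.07 for thioredoxins and glutaredoxins, -0.30 to -0.01 for mitochondrial membrane proteins, -0.21 to -0.09 for DNA replication, -0.24 to -0.01 for expansins and -0.17 to -0.04 for aquaporins. MADS-box genes (5 genes) had a median of 0.10, but -0.01 after cyclic loess, -0.13 without replicate 3 at 45 °C, -0.07 without replicate 1 at 40 °C and 0.26 without replicate 3 at 40 °C. With a minimum of 6 the medians were -0.09 for MADS-box genes, -0.12 for jasmonate, -0.37 for sucrose and trehalose, -0.30 for cytochrome P450 and 0.004 for aquaporins. Without a minimum they were -0.02 for sucrose and trehalose, 0.03 for cytochrome P450, 0.05 for expansins and 0.01 for aquaporins. Without a filter on dim probe sets MADS-box genes (adjusted p = 0.00476) and expansins (adjusted p = 0.046) passed as higher. For bZIP genes (11 genes) the median was 0.03 and the mean -0.08, and the median was -0.21 to 0.08 when leaving out 1 array, below 0 for 4 of the 6.

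The heat shock list was called lower at 45 °C by camera with the preset correlation. It was not called with an estimated correlation (adjusted p = 0.593), where no list passed. Nor was it called without replicate 1 at 40 °C (0.243), or without replicate 1 (0.106) or 3 (0.14) at 45 °C. The array of 40 °C replicate 2 as the source is argued against by the adjusted p of 0.00053 without it. The list's median lay at percentile 0.25 of random lists matched on mean expression and at 0.31 after cyclic loess. For the list as a whole, these values argue against a shift of all genes that varies with expression as the only source. The matched lists do not measure the spread between arrays. Camera ended the call after cyclic loess (adjusted p = 0.61, median -0.32 before and -0.11 after). Because camera compares a list with all other genes and not with genes of equal expression, this loss does not bear on such a shift. Whether starting abundance contributes was not settled. The 28 members with a mean below 12 had a median of -0.32, as the whole list did, and the 11 others a median of -0.21. The median of the 28 lay at percentile 3.04. The matched range was wider for these fewer genes (-0.325 to -0.091) than for the whole list (-0.268 to -0.095), so this percentile cannot decide. A response of these transcripts to temperature stays open and untested.

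Replicate 2 at 40 °C stood apart from the other arrays. A 45 °C sample under a 40 °C label was examined by correlation. The lowest correlation of this array with the other 40 °C arrays exceeded its highest with the 45 °C arrays by 0.0129. This measure cannot decide on a label, because it does not separate the groups. Replicates 2 and 3 at 45 °C correlated at 0.945 and 0.948 with replicate 3 at 40 °C, but at 0.944 with each other. Fragmented RNA or incomplete coverage is a candidate explanation for replicate 2 at 40 °C. Its 3-prime minus 5-prime difference was the highest of the 6 arrays in 5 of 5 control transcript sets. Less endosperm tissue in that sample may add to it: the median of the 8 endosperm markers differed by -0.625 from the lowest of the other arrays, although these markers were also measured in the other embryo samples at medians from 9.08 to 10.09. The markers did not fall together in that array. For RA14 and 134P10.7, those of highest signal, the log2 change hardly moved without it (-0.003 to 0.009 and 0.372 to 0.385). For all the others it moved down, as for prolamin from 0.254 to -0.321. No biological explanation was tested for a single array.

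Probe sets of middle and high signal were lower at 45 °C. Replicate 2 at 40 °C as the cause is argued against by a median change of -0.14 without it (-0.1429). Lower RNA integrity at 45 °C stays open: the mean 3-prime minus 5-prime difference at 45 °C differed by -0.045 from that of the 2 other 40 °C arrays, and that of ubiquitin, 1 of 5 sets, was lower on all 45 °C arrays (difference -0.79), both against it, but the mean 3-prime minus middle difference was higher on all 3 arrays at 45 °C than on those 2, by a mean of 0.37. Less rice mRNA target relative to other RNA may contribute but stays open too. The controls bioB (1.502 higher at 45 °C), bioC (0.83 higher) and 4 of 5 ribosomal RNA probe sets were separated between groups. Those that overlapped were bioD (0.28), cre (0.02) and the 5.8S probe set. The overlap of cre tells little, because at 14.4 to 14.5 it lay near the highest values of the arrays (14.5 to 14.6). Neither lower RNA integrity nor less mRNA target can be told apart from a loss of transcripts in the seeds, which was not tested.

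The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 0 adjusted calls with limma and the highest other split 0, so that 10 of 10 splits gave as many. With 0 calls in the real split this outcome was fixed, so it tells nothing about chance. At an unadjusted p under 0.05 the real split gave 4256 probe sets and the highest other split 1637, so that 1 of 10 splits gave as many. For the heat shock list the camera p was 9.77e-04 in the real split and 0.00111 in the other split with the smallest p. Thus 1 of 10 splits gave a p as small. All other splits place both temperatures in each group, where a temperature difference widens the within-group spread. They are therefore not a clean measure of chance.

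Probe sets for genes of the rice blast fungus, controls on the array, had median log2 values of 2.26 at 40 °C and 2.54 at 45 °C. The highest value among them on each array averaged 3.81 at 40 °C and 3.68 at 45 °C, with the groups overlapping. All these values lie under the expression minimum of 4, so they do not show more fungal transcript at 45 °C.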
